A study of Mus musculus with 3 samples.

How the data were processed

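Libraries were made, per the labels, with the 10x Genomics Chromium 3′ kit from primary mouse tracheal epithelial cells on day 5 at the air-liquid interface, after electroporation of Cas9 protein with a control nontargeting guide, a guide targeting Gmnc or a guide targeting Mcidas. There was 1 library per group. The submitters' processing notes list Cell Ranger 3.0 and the mouse build mm10, whereas the file headers name Cell Ranger 4.0.0. Other upstream steps are not given in the sources used here, except that the names of libraries in the authors' cell table contain the word soupx, the name of a tool that corrects for free RNA, and that its pseudotime columns contain the word sling. The deposited matrix of each library holds raw UMI counts per gene and barcode, as whole-number counts over 31053 features. The deposited combined matrix holds estimated counts, that is, expected counts after the authors' free RNA correction, which are not whole numbers. The deposited cell table gives, for the cells that the authors kept, the library, a cluster number from 1 to 11 without names, the expected counts per cell, the percent of those counts in mitochondrial genes, and a pseudotime score along each of the paths whose names stand for multiciliated and secretory cells. Another 5 columns of that table were not used here, nor was the deposited normalized matrix.

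The control, Gmnc-labelled and Mcidas-labelled matrices held 14140, 13174 and 12333 barcodes, of which the authors kept 5266, 4949 and 4713. Kept cells had at least 3012 genes, at most 99991 UMIs and at most 12.5% mitochondrial counts. A further 276, 277 and 123 barcodes lay inside the kept ranges but were left out by the authors for reasons not given in the sources used here. Median UMIs per kept cell were 42612, 35860 and 34340, median genes 6169, 5661 and 5460, and median mitochondrial percentages 7.72, 8.31 and 8.44. Raw UMI counts of the kept cells were used for the main values. The authors' correction removed a median of 4.71%, 4.44% and 6.61% of the UMIs of a cell. The corrected matrix has 20772 rows without names, so 18242 of them, which hold 99.4% of its counts, were matched to genes by their values across cells (cosine of at least 0.95, and a distance at most 0.5 of that to the next best gene). These corrected counts served only as an alternative.

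Of the 31053 features, 30934 gene identifiers were found in the GENCODE M21 annotation of mm10 (GRCm38), 30468 of them with the same symbol, and gene positions are 1-based from that annotation. Dnai1 and Dnai2 were read under their older symbols Dnaic1 and Dnaic2, and Tctn2 was not measured here.

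Clusters were named from 12 marker lists fixed before the data were examined. The 10 leading genes of a cluster, ranked by fold over all other cells with 5 CPM added to both sides, were compared with these lists. Clusters 3, 4 and 5 have 4, 2 and 1 multiciliated markers among them, and 24, 28 and 22 early or late multiciliated markers at 10 CPM or more. Other clusters have at most 12 such markers, and cluster 2 has Gmnc alone among its leading genes and 8 markers at 10 CPM. Clusters 3 and 4 were called early multiciliated-like and cluster 5 late multiciliated-like, and clusters 3 to 5 form the multiciliated class of 2176 cells. Clusters 1, 6 and 11 were called basal-like, secretory-like and cycling-like, with 3, 5 and 3 markers of those classes. Cluster 6 also has 1 leukocyte marker. Cluster 2 keeps its number although Gmnc, an early multiciliated marker, was its only match. The others keep their number because no class, or several, matched. Mcidas leads cluster 3 and Gmnc is among the leading genes of cluster 2, so both clusters are partly defined by the targeted genes. As a check of cells that the authors did not place, a nearest-neighbour classifier was fitted to the kept cells. It gave kept cells their own cluster in 95.4% of cases and the right multiciliated or other call in 99.3%, and it was used to place the left-out barcodes. A separate Leiden clustering (resolution 1.0, 15 neighbours, 30 principal components of 2000 variable genes) was run with and without the multiciliated regulators. A Leiden cluster was called multiciliated-like when a multiciliated marker was among its 10 leading genes and at least 15 markers reached 10 CPM, a minimum that was set after the clusters were seen.

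UMIs were summed over the cells of each library, or of each library within a cluster, and scaled to CPM. Log2 ratios were taken after adding 0.5 CPM to each library, and plain folds are ratios of CPM without it. Genes below 1 CPM in both libraries over all cells, or below 5 CPM within a class, were not counted as measured. List medians and named genes within classes were compared where both libraries held at least 50 cells. Levels and shares of single genes and summed lists are also given for smaller classes. Shares of cells with a UMI were computed with and without thinning every cell to 5000 UMIs, and cluster 9 served as the background for free RNA. Intervals are exact Poisson (CPM) or exact Clopper-Pearson binomial (shares) intervals at 95%, and a count of 0 was set to 3 counts for bounds. No test, p-value or count of changed genes was computed across cells, because cells of 1 library are not replicates.

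Gene lists were fixed before the data were examined. There were 22, and they cover multiciliated regulators, centriole biogenesis, ciliary motility, intraflagellar transport, the BBSome and transition zone, S phase, G2/M, basal cells, secretory cells, hillock and squamous cells, the Notch pathway, tuft cells, ionocytes, neuroendocrine cells, p53 response, dissociation stress, interferon response, fibroblasts, leukocytes, endothelial cells, cholesterol synthesis, and hypoxia and glycolysis. For each list the median log2 ratio, the number of members at least 2-fold higher or lower, and the percentile of the median among 10000 random lists of the same size matched on expression in 20 bins were computed. Medians are also described by bootstrap intervals from 2000 draws over members. Genes were named by a fixed rule. Over all cells it took the 10 highest and 10 lowest log2 ratios at 10 CPM or more in the higher library. Within clusters 3 to 5, and within each cluster, it took 8 and 8 at 50 CPM or more and 50 UMIs. Predicted genes were passed over. The rule also took up to 4 members of each list, every multiciliated regulator, and the 5 leading genes of each cluster. A few genes that the rule takes are not reported here. Genes of the Mycl-led Leiden cluster and those named for other clusters in the closing observations were chosen after their values were seen.

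The alternatives planned before the data were examined were TMM factors and size factors, pseudocounts of 0.1 and 2, per-cell means, thinned counts, thinning to 2000 or 10000 UMIs, all barcodes with at least 500 genes, a stricter cell filter (2000 genes and 10% mitochondrial counts), Scrublet doublet calls, other minimums for counting a list member as measured, another seed for thinning, the marker rule and Leiden clusters. The alternatives chosen after seeing the data were the corrected counts, the removal of the 5% of cells with the highest Scrublet scores, matching on pseudotime, Leiden clusters without regulators or with the Mycl-led cluster, and the runs on cluster 3 alone. Scrublet at its default threshold called 1 of 14928 cells and so did not separate doublets. Kept cells already had at least 3012 genes, so the stricter cell filter acted through its mitochondrial limit only.

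The code was tested on simulated data drawn from the control library's profile. With 200 genes altered by 1 or 2 log2 units, 98% to 100% lay within 0.25 of the log2 ratio expected after adding 0.5 CPM. Of 12603 unaltered genes 0 were at least 2-fold apart, and 95.2% and 95% of counting intervals held the simulated ratio. The draws held counting error only, with no difference between cultures or in cell composition. They check the code and give no error rate for differences between these libraries. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 was used only for TMM factors.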

Results

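Single-cell RNA was measured in 3 libraries of primary mouse tracheal epithelial cells, a culture of the airway lining that forms basal, secretory and multiciliated cells once its upper surface is exposed to air. Per the labels, the cells were expanded, electroporated with Cas9 protein bound to a guide RNA, reseeded, differentiated and dissociated with trypsin on day 5 at the air-liquid interface. One group received a nontargeting control guide, another a guide targeting Gmnc and another a guide targeting Mcidas, with 1 library in each group. Gmnc and Mcidas are related coiled-coil proteins that start multiciliated cell differentiation, and Mcidas acts with the E2f4 and E2f5 transcription factors. The cells that the authors kept numbered 5266 in the control library, 4949 in the Gmnc-labelled library and 4713 in the Mcidas-labelled library. Those cells held 237268278, 199156575 and 175560458 unique molecular identifiers (UMIs), with medians of 42612, 35860 and 34340 UMIs per cell. With 1 library per group there was no spread between replicates, so no difference was tested. The 95% intervals given are exact Poisson intervals for CPM (UMI counts of a gene scaled by the total UMIs of its library or cluster) and exact binomial intervals for shares, and they cover counting error only. Each difference between guides is therefore also a difference between cultures.

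The targeted genes differed between the libraries in opposite ways. Gmnc mRNA was 4.99-fold higher in the Gmnc-labelled library than in the control, and Mcidas mRNA was 2.46-fold lower in the Mcidas-labelled library than in the control. Gmnc (ENSMUSG00000068428; mm10 chromosome 16, 26913553 to 26991652, minus strand, protein coding) stood at 9.57 CPM in the control (9.18 to 9.97), 47.8 CPM in the Gmnc-labelled library (46.8 to 48.8) and 23.9 CPM in the Mcidas-labelled library (23.2 to 24.6). Mcidas (ENSMUSG00000074651; mm10 chromosome 13, 112993845 to 113000394, plus strand, protein coding) stood at 19.7 CPM in the control, 8.74 CPM in the Gmnc-labelled library (8.33 to 9.16) and 8.0 CPM in the Mcidas-labelled library (7.59 to 8.43). Ccno, the cyclin O gene, lies beside Mcidas at 112987802 to 112990777 on the same strand. The UMIs come from the 3′ ends of transcripts and do not read the guides' target sites, so they do not show how many cells were edited, and the libraries are named here by their labels.

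Within clusters the targeted genes again differed, but a cluster held different cells in each library. In the Leiden clustering described below, 35 of 146 control, 36 of 55 Gmnc-labelled and 243 of 245 Mcidas-labelled cluster 3 cells fell in a Mycl-led cluster. So did 2.45%, 0.644% and 30.4% of cluster 2 cells, and 16 of 64 Mcidas-labelled but 0 of 965 control cells of cluster 5. In cluster 2, of which Gmnc is a leading gene, Gmnc stood at 17.5 CPM in the control, 77.0 CPM in the Gmnc-labelled library and 34.1 CPM in the Mcidas-labelled library. In cluster 3, which Mcidas itself leads, Mcidas stood at 232 CPM in the control (221 to 243), 129 CPM in the Gmnc-labelled library (116 to 143) and 47.9 CPM in the Mcidas-labelled library (43.8 to 52.2). In clusters 2, 4 and 5 Mcidas was higher in the Mcidas-labelled library than in the control, at 5.72 against 2.39 CPM in cluster 2, 137 against 103 CPM in cluster 4 (33 Mcidas-labelled cells) and 4.75 against 1.72 CPM in cluster 5 (14 UMIs in the Mcidas-labelled library). It stood at 1.39 against 2.40 CPM in cluster 6, with 13 and 36 UMIs, and at 2.04 against 1.89 CPM in cluster 1, each with overlapping intervals. Over clusters 3 to 5 it stood at 50.9 CPM in the Mcidas-labelled library (47.4 to 54.5) and 54.5 CPM in the control (52.9 to 56.1), with overlapping intervals. In cluster 2, 15.3% of Mcidas-labelled cells and 8.37% of control cells had a Mcidas UMI. Gmnc in cluster 3 stood at 6.61 CPM in the control (4.91 to 8.72), 38.3 CPM in the Gmnc-labelled library (31.5 to 46.2) and 41.1 CPM in the Mcidas-labelled library (37.3 to 45.0). At least 1 Gmnc UMI was seen in 24.1% of control cells, 51.4% of Gmnc-labelled cells and 39.9% of Mcidas-labelled cells. In cluster 9, a fibronectin-rich cluster taken as background for free RNA, those shares were 3.11%, 12.2% and 6.76%, at median depths of 46285, 46029 and 38472 UMIs. For Mcidas the shares were 13.9%, 8.49% and 14.1% of cells, against 2.00%, 0.995% and 0.932% in cluster 9. These depths differ between libraries, and after each cell was thinned to 5000 UMIs the Mcidas shares were 5.36% (4.76 to 6.0), 2.28% (1.89 to 2.74) and 2.95% (2.49 to 3.47).

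The design asks first whether multiciliated cells form when Gmnc or Mcidas is targeted. Multiciliated-like cells were a smaller share of both guide libraries. The authors' table gives 11 clusters without names, and clusters 3, 4 and 5 were called multiciliated-like from fixed markers. Together they held 28.9% of control cells (27.7 to 30.2), 6.30% of Gmnc-labelled cells (5.64 to 7.02) and 7.26% of Mcidas-labelled cells (6.53 to 8.04). The stages differed between the guide libraries. Cluster 3, the earliest of these along the authors' multiciliated path and led by Mcidas, Ccno, E2f7, Myb and Dtl, held 2.77% of control cells (2.35 to 3.25), 1.11% of Gmnc-labelled cells (0.838 to 1.44) and 5.20% of Mcidas-labelled cells (4.58 to 5.87). Cluster 4, led by the deuterosome gene Deup1 and by Ccna1, Cox6b2, Ccdc18 and Mdm1, held 411 control, 123 Gmnc-labelled and 33 Mcidas-labelled cells. Cluster 5, led by the late ciliary genes Calml4, Sntn, Myl4, Fam183b and Efcab10, held 18.3% of control cells (17.3 to 19.4), 2.71% of Gmnc-labelled cells (2.27 to 3.20) and 1.36% of Mcidas-labelled cells (1.05 to 1.73). The control share of cluster 5 was 6.77-fold that of the Gmnc-labelled library and 13.5-fold that of the Mcidas-labelled library. Cluster 3 made up 71.6% of the multiciliated-like cells of the Mcidas-labelled library (66.5 to 76.4), against 17.6% in the Gmnc-labelled library (13.6 to 22.3) and 9.59% in the control (8.16 to 11.2).

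**Figure D1:**
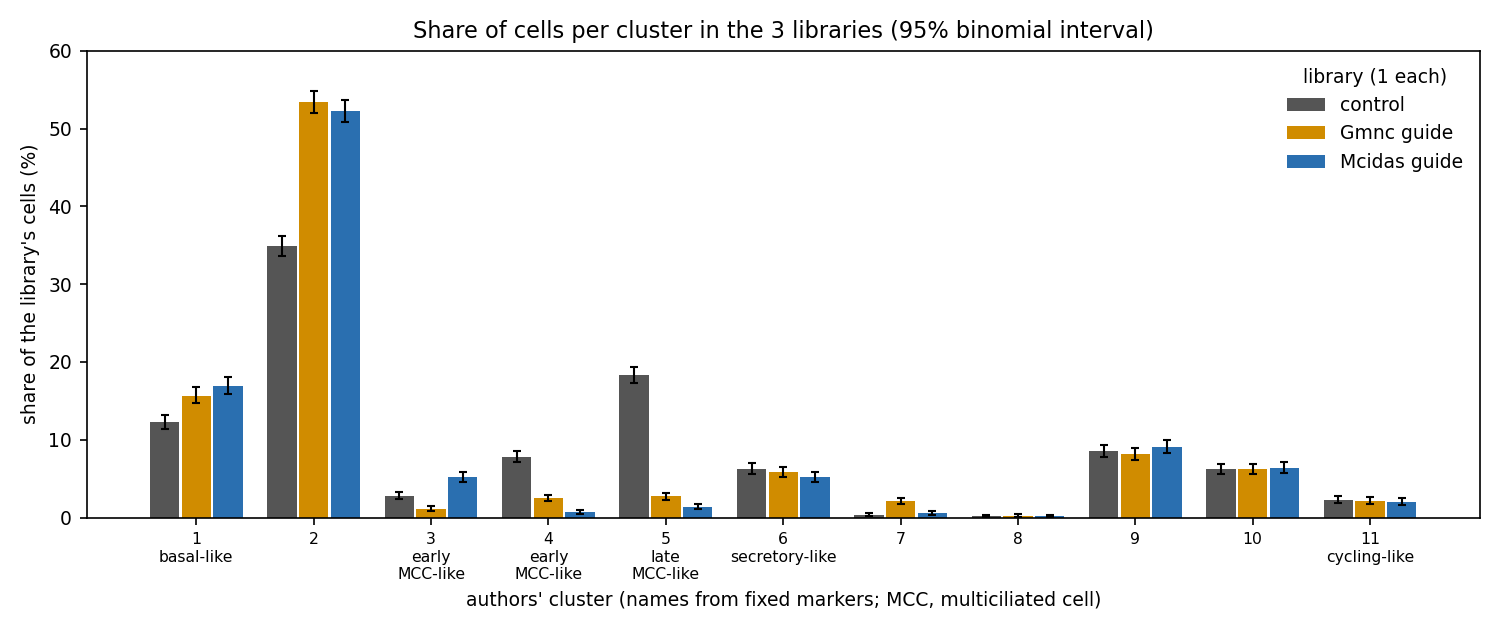
The bars give the percentage of each library's kept cells in each of the authors' 11 clusters, for the control, Gmnc guide and Mcidas guide libraries (1 library each), with exact 95% binomial intervals. Cluster 5 stands at 18.3% in the control against 2.71% and 1.36% in the guide libraries, and cluster 2 at 34.9% against 53.4% and 52.3%.

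Of the other clusters, 1 and 2 were larger shares of both guide libraries, and 7 of the Gmnc-labelled library, beyond counting error. The smaller share of clusters 3 to 5 in the guide libraries by itself raises the shares of all other clusters. Shares among the cells outside clusters 3 to 5 were not computed, so no gain or loss of those cell types is read. Cluster 2, led by A2ml1, Acsm1, Aox3 and Gmnc, held 34.9% of control cells, 53.4% of Gmnc-labelled cells (52.0 to 54.8) and 52.3% of Mcidas-labelled cells (50.8 to 53.7). The basal-like cluster 1, led by Hlf, Dapl1, Defb1, Cyp3a13 and Aqp3, held 12.2%, 15.7% and 17.0%. Cluster 7, led by the interferon-induced genes Ifit3, Isg15, Ifit3b, Ifit1 and Rtp4, held 0.342% of control cells (0.203 to 0.540), 2.06% of Gmnc-labelled cells (1.68 to 2.50) and 0.530% of Mcidas-labelled cells (0.344 to 0.782). With 102 of its 145 cells in the Gmnc-labelled library, cluster 7 may be a property of that library and not a cell type. The secretory-like cluster 6, led by Muc5b, Scgb3a1, Pigr, Bpifb1 and Lyz2, held 6.29%, 5.84% and 5.22%. The cycling-like cluster 11, led by Pclaf, Ube2c, Mki67, Birc5 and Hist1h2ap, held 2.32%, 2.16% and 2.06%. Cluster 9 (Mmp13, Fn1, Ppbp, Inhba and Tnfrsf11b) held 8.55% of control, 8.12% of Gmnc-labelled and 9.10% of Mcidas-labelled cells, and cluster 10 (Krt6a, Ly6d, Krt5, Cxcl5 and Ccnd2) held 6.23%, 6.20% and 6.41% of the control, Gmnc-labelled and Mcidas-labelled cells. Cluster 8 (Gnat3, Chga, Lrmp and Nov), which mixes markers of neuroendocrine and tuft cells and ionocytes, held 31 cells.

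Because regulators lead clusters 2 and 3, cells were also grouped anew with Leiden clustering, with and without the listed multiciliated regulators. That clustering placed 1026 cells, 21.8% of the Mcidas-labelled library (20.6 to 23.0), in a cluster led by Mycl, Pidd1, Pnpla2, Paqr4 and Cdt1, with Ccno, E2f7 and Dtl among its leading genes. The same cluster held 1.56% of control cells and 1.07% of Gmnc-labelled cells. Of the 1026 cells, 748 belonged to the authors' cluster 2 and 243 to their cluster 3. The Mycl-led cluster had 12 multiciliated markers at 10 CPM (14 when grouped without the regulators), under a minimum of 15 that was set after the clusters were seen, and so was not counted as multiciliated-like. Grouping without the regulators gave 1.75%, 1.31% and 20.3%. The multiciliated-like share of the Mcidas-labelled library was 1.78% on this clustering, or 23.6% with the Mycl-led cells counted in, and 4.02% when all barcodes with at least 500 genes were used. With all those barcodes cluster 3 held 3.20% of the Mcidas-labelled library and 2.42% of the control. A rule that asks for 3 late or early multiciliated markers per thinned cell gave 54.5%, 24.4% and 22.9% of cells, but it was met by 48.0%, 26.3% and 22.4% of the basal-like cluster 1 cells, 37.0%, 21.2% and 21.3% of the cluster 2 cells and 20.0%, 4.98% and 2.56% of the cluster 9 cells, so it does not measure the multiciliated share.

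Shares that do not rest on clusters were also lower in both guide libraries for most of the ciliary and centriole genes examined. After each cell was thinned to 5000 UMIs, Foxj1, the master transcription factor of motile cilia (mm10 chromosome 11, 116330704 to 116335399, minus strand), was seen in 32.8% of control cells (31.5 to 34.1), 9.58% of Gmnc-labelled cells (8.77 to 10.4) and 6.26% of Mcidas-labelled cells (5.58 to 6.99). Without thinning, the shares were 59.1%, 25.6% and 19.1%. The cluster 9 background at 5000 UMIs was 9.56%, 5.97% and 3.26%. Dnah5, an outer dynein arm heavy chain, was seen in 26.6%, 5.05% and 1.49% of cells, against 2.00%, 0.995% and 0 of 429 cells in cluster 9. Tppp3 was seen in 37.6%, 7.96% and 3.33%, with 10.2%, 2.74% and 0.466% in cluster 9. Rsph1, a radial spoke gene, was seen in 33.4%, 8.24% and 4.69%, with 6.0%, 3.48% and 0.699% in cluster 9. Deup1 was seen in 12.1%, 3.62% and 3.57% of cells, and Plk4, the kinase that starts centriole assembly, in 8.19%, 3.60% and 2.25%. Their cluster 9 shares were 0.889%, 0% and 0.466% for Deup1 and 2.22%, 0.249% and 2.10% for Plk4, so Plk4 in the Mcidas-labelled library was not above background. Ccno was seen in 13.3%, 11.1% and 13.8% of cells although its CPM was lower in both guide libraries, and no order is read from it.

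The Gmnc-labelled library was compared with the control to ask what a guide against Gmnc does to differentiating airway cells. Over all cells, all 40 measured ciliary motility genes were at least 2-fold lower, with a median log2 ratio of -2.21. Centriole, intraflagellar transport and transition zone genes were lower too, basal cell markers were a little higher, and some interferon-induced genes were higher. Tubb4b, a tubulin of ciliary axonemes, stood at 2730 CPM in the control and 1027 CPM in the Gmnc-labelled library, the dynein light chain Dynlrb2 at 976 and 212 CPM, Tppp3 at 961 and 181 CPM and Ccdc153 at 647 and 132 CPM. In the centriole list 15 of 29 genes were at least 2-fold lower (median -1.03), among them Cetn2 (319 and 130 CPM), Cetn4 (209 and 43.3 CPM) and Deup1 (94.0 and 33.0 CPM), while Pcm1 stood at 192 and 129 CPM. Of the intraflagellar transport genes 17 of 20 were at least 2-fold lower (median -1.33), with Ift43 at 260 and 106 CPM and Ift74 at 75.7 CPM in the Gmnc-labelled library. Of the BBSome and transition zone genes 13 of 20 were (median -1.20), with B9d1 at 181 and 77.2 CPM and Cep290 at 157 and 63.4 CPM. All of these medians lay at percentile 0 of 10000 random lists matched on expression, as a description of these libraries.

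Among the 20 multiciliated regulators 11 were at least 2-fold lower and 1, Gmnc, was higher in the Gmnc-labelled library, with a median of -1.09. Foxj1 stood at 256 CPM in the control and 71.8 CPM in the Gmnc-labelled library, Myb at 94.9 and 30.1 CPM, Ccna1 at 71.5 and 19.6 CPM, and Trp73, which encodes the p53 relative p73, at 8.67 and 2.13 CPM. Rfx2 (18.3 and 6.33 CPM), Rfx3 (39.3 and 12.4 CPM), Foxn4 (6.38 and 2.27 CPM), Cdc20b (6.19 and 2.19 CPM), Fbxo43 (5.14 and 1.77 CPM) and E2f7 (13.1 and 6.02 CPM) were each at least 2-fold lower. Cdk1 (73.6 and 36.8 CPM), Ccno (77.4 and 41.5 CPM) and Hes6 (167 and 88.8 CPM) were lower without passing the 2-fold mark on the scale with 0.5 CPM added. E2f4, E2f5 and Tfdp1, the partners through which Mcidas acts, stood at 23.0, 22.3 and 24.1 CPM against 23.6, 22.4 and 25.1 CPM in the control. Gmnn stood at 24.2 against 30.7 CPM, and the cell cycle inhibitor gene Cdkn1a at 547 against 653 CPM.

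The 10 genes with the lowest ratios between the Gmnc-labelled library and the control were Ldlrad1, Ppp1r36, Sftpc, Cdhr4, Myl4, Timp4, Ampd1, Lbh, Ccdc33 and Calml4, with log2 ratios of -2.78 to -2.61. Ldlrad1 stood at 41.5 and 5.59 CPM, Sftpc at 68.7 and 10.1 CPM, and Calml4, a calmodulin-like gene, at 122 and 19.6 CPM. After Gmnc (log2 ratio 2.26), the highest ratios belonged to Ifit3 (3.60 and 18.8 CPM), Isg15 (13.9 and 47.6 CPM), the squamous gene Ivl (6.50 and 15.4 CPM), Xaf1, Phf11d, Ankrd1, Oasl2, Gfra1 and Sulf1. In selecting these genes, 4 predicted genes with lower ratios and none with higher ratios were passed over.

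The remaining lists differed less between the Gmnc-labelled library and the control. Interferon response genes had a median of 0.77 with 4 of 20 at least 2-fold higher (percentile 100), but Usp18 went the other way, at 37.8 against 70.4 CPM. Basal cell markers had a median of 0.39 (0 of 14 past 2-fold, percentile 100), with Krt15 at 3874 against 3004 CPM and Krt17 at 267 against 220 CPM. That rise was not separated from the smaller part of UMIs in multiciliated-like cells. The hillock and squamous list had a median of 0.18 (2 of 16 higher), the S phase list 0.02 (1 of 44 past 2-fold), the G2/M list -0.54 (8 of 52 lower, percentile 0) and the secretory list -0.02 (2 of 18 lower). Within the secretory list Reg3g stood at 16139 against 15264 CPM and Cyp2f2, a club cell cytochrome P450, at 14040 against 9217 CPM. Medians were -0.13 for the Notch pathway, with its target gene Hes1 at 298 against 196 CPM, 0.10 for the p53 response, 0.22 for dissociation stress, -0.24 for cholesterol synthesis and 0.15 for hypoxia and glycolysis. Neuroendocrine markers had a median of 0.88 over 4 genes, with Chga at 1.87 against 0.110 CPM. Ionocyte markers had a median of -0.57 over 4 genes, and leukocyte markers one of 0.24 over 4 genes, of which Cd14 and Lyz2 are also expressed by airway epithelium. Tuft and fibroblast lists had 2 measured genes each and no median, with Gng13 at 4.54 against 15.9 CPM, and no endothelial gene reached the 1 CPM floor in any comparison.

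**Figure D2:**
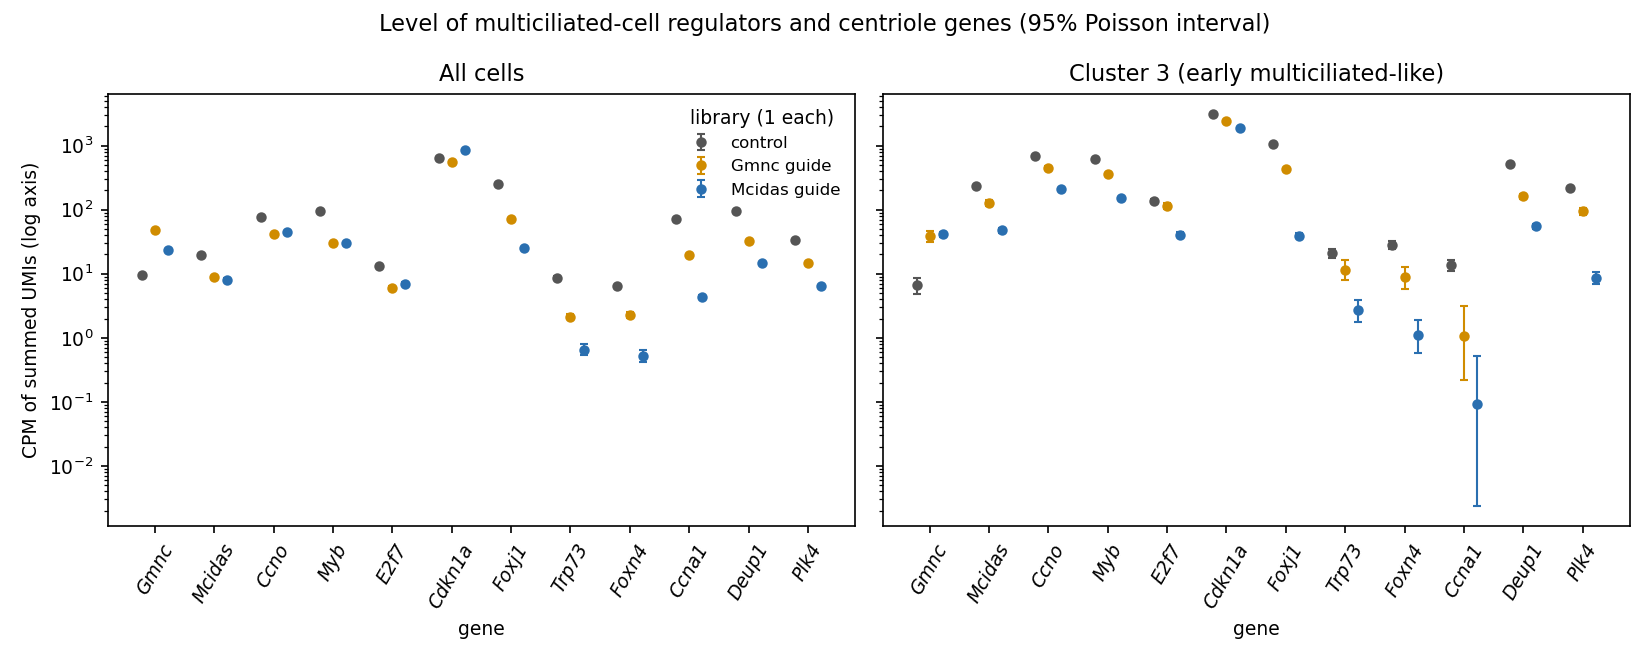
The points give CPM on a log axis for 12 regulator and centriole genes in each library (1 each), over all cells and within cluster 3, with exact 95% Poisson intervals. In cluster 3 Foxj1 stands at 1080 CPM in the control, 430 CPM in the Gmnc guide library and 39.4 CPM in the Mcidas guide library, while Gmnc stands at 6.61, 38.3 and 41.1 CPM.

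Taken over clusters 3 to 5, the multiciliated-like cells of the Gmnc-labelled library were close to control cells in their ciliary and centriole genes. In clusters 3 to 5 the ciliary motility median was -0.29, with 0 of 40 genes past 2-fold, and the centriole median was 0.22, with 0 of 29. The regulator median was 0.27, intraflagellar transport -0.22, BBSome and transition zone -0.11, S phase 0.33 and G2/M 0.28. Foxj1 stood at 714 CPM in the control and 723 CPM in the Gmnc-labelled library, Deup1 at 271 and 377 CPM, and Mcidas at 84.4 CPM in the Gmnc-labelled library. The highest ratios were those of Aqp5 (125 and 291 CPM), Tgm2, Msln, the iron carrier gene Trf, Lcn2, Rps28, Ltf and Mycl (29.8 and 52.0 CPM), and the lowest those of Scgb3a1, Scgb3a2, Lbh, B3galt2, Ldlrad1, Ppp1r36, Serpinb12 and Timp4. Cluster 5 held 965 of the 1522 control cells but only 134 of the 312 Gmnc-labelled cells, so these values mix stages. Within cluster 4 the ciliary median was -0.16 and within cluster 5 it was -0.01.

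In cluster 3 alone, the early stage, the Gmnc-labelled cells (55 cells) differed more from the control cells (146 cells). The class holds different cells in each library, since 110 of the control cells but 18 of the Gmnc-labelled cells fell in a Leiden cluster led by Deup1, Hyls1 and Plk4, and 35 and 36 in the Mycl-led cluster. The ciliary motility median was -2.34 (37 of 38 lower) and the centriole median -1.38 (21 of 28 lower). Regulators had a median of -0.79, intraflagellar transport genes -1.22, BBSome and transition zone genes -1.06 and G2/M genes -1.40, whereas 5 of 6 basal markers were at least 2-fold higher (median 1.25, or 0.23 with no minimum for counting a gene as measured). Foxj1 stood at 1080 CPM in the control and 430 CPM in the Gmnc-labelled library, Deup1 at 508 and 162 CPM and Plk4 at 217 and 94.5 CPM. Timp3 (13.6 and 98.4 CPM), Tgfb2, Aqp3, the cyclin gene Ccnd1 (32.3 and 94.9 CPM), Btg2, Chp1 and Aox3 had the highest ratios, and Dmkn, Ccdc153, Cfap161, Tmem212, Hpgd, Tm4sf1, Spag6l and Crocc2 the lowest. The median position on the authors' path was 15.5 in the Gmnc-labelled library and 17.3 in the control. Weighted to matched positions from 14 to 18, an alternative chosen after seeing the data, the centriole median was -0.81, the ciliary median -1.93, the G2/M median -0.63, the regulator median -0.29 and the basal median 0.84. Over all alternatives the intraflagellar transport median ran from -1.25 to -0.742 and the BBSome and transition zone median from -1.21 to -0.561.

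The Mcidas-labelled library was compared with the control to ask the same of Mcidas. All 40 ciliary motility genes were again at least 2-fold lower over all cells, with a median of -3.97, and Mycl, Gmnc and Serpinb2 were at least 2-fold higher. Centriole, transport and transition zone genes were lower, and basal markers were a little higher. Tubb4b stood at 736 CPM against 2730 CPM in the control, Dynlrb2 at 54.9 against 976 CPM, Tppp3 at 55.9 against 961 CPM and Ccdc153 at 29.5 against 647 CPM. In the centriole list 23 of 29 genes were at least 2-fold lower (median -1.58), with Cetn2 at 91.6 against 319 CPM and Deup1 at 14.8 CPM. Of the intraflagellar transport genes 18 of 20 were lower (median -1.86), with Ift20 at 120 against 285 CPM and Ift22 at 51.8 against 214 CPM. Of the BBSome and transition zone genes 16 of 20 were lower (median -1.74), with B9d1 at 58.8 against 181 CPM and Cep290 at 46.2 against 157 CPM. The percentile was 0 for each of these lists. Scaling by TMM moved the median of all genes from -0.07 to 0.10, and size factors moved it to 0.07, for the Mcidas-labelled library against the control, and from -0.18 to 0.07 and 0.08 in clusters 3 to 5. Between the Mcidas-labelled and Gmnc-labelled libraries in clusters 3 to 5 it moved from -0.15 to 0.09 and 0.08.

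The regulator list had a median of -1.21 in the Mcidas-labelled library, with 11 of 20 at least 2-fold lower and 1, Gmnc, higher. Foxj1 stood at 25.3 CPM against 256 CPM, Myb at 29.8 against 94.9 CPM, Ccna1 at 4.26 against 71.5 CPM, Trp73 at 0.655 against 8.67 CPM, Foxn4 at 0.518 against 6.38 CPM, Fbxo43 at 0.450 against 5.14 CPM and Cdc20b at 1.3 against 6.19 CPM. Rfx2 (3.86 CPM), Rfx3 (6.85 CPM) and Cdk1 (32.5 CPM) were at least 2-fold lower too. Ccno (45.6 CPM), E2f7 (7.02 CPM) and Hes6 (88.3 CPM) were lower by less than 2-fold. Cdkn1a stood at 863 against 653 CPM, and E2f4, E2f5, Tfdp1 and Gmnn stood at 23.8, 20.0, 25.6 and 20.6 CPM.

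The lowest ratios between the Mcidas-labelled library and the control belonged to Sftpc, Fam183b, Odf3b, Calml4, Efcab10, Ccdc153, Sntn, Dmkn, Tctex1d4 and Timp4. Sftpc, the surfactant protein C gene, was 31.5-fold lower, at 2.18 against 68.7 CPM, and Sntn, which marks the tips of motile cilia, stood at 8.07 against 184 CPM. Fam183b stood at 17.1 against 396 CPM. The highest ratios were those of Mycl, which encodes the transcription factor L-Myc, at 93.9 against 29 CPM (3.24-fold), followed by Gmnc, Serpinb2, Rps28, Ccr2, Ankrd1, Hist1h2ap, Gfra1, mt-Atp8 and Sytl2. The predicted genes passed over numbered 1 with a higher and 6 with a lower ratio.

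The other lists had medians within 1 log2 unit of 0 between the Mcidas-labelled library and the control. Medians were 0.43 for basal markers (percentile 100), with Krt15 at 4302 against 3004 CPM and Krt14 at 139 against 103 CPM, and 0.27 for the hillock and squamous list. The secretory median was -0.26 (6 of 18 lower), with Reg3g at 13468 CPM and Cbr2 at 12640 against 8660 CPM. The p53 response median was 0.30 with 0 of 19 past 2-fold, with Cdkn1a and Btg2 (620 against 452 CPM) among its members. S phase genes had a median of 0.00, G2/M genes -0.76 (20 of 52 lower), the Notch pathway -0.08, dissociation stress -0.05, interferon response 0.09, cholesterol synthesis -0.37, and hypoxia and glycolysis 0.19. Fdps and Hmgcs1 of the cholesterol list stood at 73.7 against 145 CPM and 60.5 against 149 CPM. Tuft markers had a median of 0.45 over 3 genes, ionocyte markers -0.60 over 4, neuroendocrine markers -0.89 over 3 and leukocyte markers 0.06 over 4. The fibroblast list had 2 measured genes, Dcn at 3.23 against 3.19 CPM and Vim at 0.108 against 2.01 CPM.

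Within the multiciliated-like clusters the Mcidas-labelled cells held less ciliary and centriole mRNA than control cells. In clusters 3 to 5 the ciliary motility median was -2.22 with 40 of 40 genes at least 2-fold lower, and 21 of 29 centriole genes were lower (median -1.43). These cells were mostly cluster 3 (245 of 342), whereas those of the control were mostly cluster 5 (965 of 1522). Of the cluster 3 cells, 243 of 245 in the Mcidas-labelled library but 35 of 146 in the control fell in the Mycl-led Leiden cluster, and 2 and 110 in the Deup1-led one, so different cells are compared. In cluster 3 alone the ciliary motility median was -5.03 with 38 of 38 lower, and the centriole median was -2.55 with 27 of 28 lower. Foxj1 stood at 39.4 against 1080 CPM, Deup1 at 54.8 against 508 CPM, Plk4 at 8.56 against 217 CPM and Trp73 at 2.67 against 20.9 CPM. Myb (150 against 629 CPM), Ccno (209 against 691 CPM) and E2f7 (40.6 against 136 CPM) were lower as well. Dynlrb2 stood at 0.920 against 814 CPM, Ccdc153 at 0.460 against 253 CPM, Tppp3 at 4.51 against 889 CPM and Tekt1, a tektin of the axoneme, at 0.552 against 182 CPM. Ccna1 had a single UMI there, a level of 0.0920 CPM against 13.6 CPM. Regulators had a median of -1.96 (13 of 20 lower), intraflagellar transport genes -2.02, BBSome and transition zone genes -1.94, and G2/M genes -1.87 (29 of 37 lower). Medians with members at 0 placed at their bound were the same to 2 decimals. At matched positions the centriole median was -2.0.

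Genes higher in the cluster 3 cells of the Mcidas-labelled library were led by Timp3 (66.6 against 13.6 CPM), the recombination gene Rad51b (129 against 31.3 CPM), Ccnd1 (120 against 32.3 CPM), Lpar1, Pygb, Lrrc26, Xbp1 and Tgfb2. Lrrc23, BC051019, Tm4sf1 and Cfap161 were among the lowest. In clusters 3 to 5 together the highest ratios were those of Akr1c18, Acsm1, Tgm2, Mycl (203 against 29.8 CPM), Cyp2a5, Aqp5, Msln and Epb41l4aos, and the lowest those of Sftpc, Fam166b, Timp4, Ppp1r36, Odf3b, Dthd1, Prr18 and Lbh. Basal markers had a median of 1.23 with 4 of 7 at least 2-fold higher, which was 0.18 with no minimum for counting a gene as measured and 2.03 with the corrected counts, and Krt15 stood at 2206 against 376 CPM. In cluster 5, with 64 Mcidas-labelled cells, the ciliary median was -0.78 and the centriole median -0.60. Of these 64 cells 16 fell in the Mycl-led Leiden cluster, against 0 of 965 control cells, so different cells are compared there too. List medians and named genes were not compared in cluster 4, since the Mcidas-labelled library had 33 cells there.

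**Figure D3:**
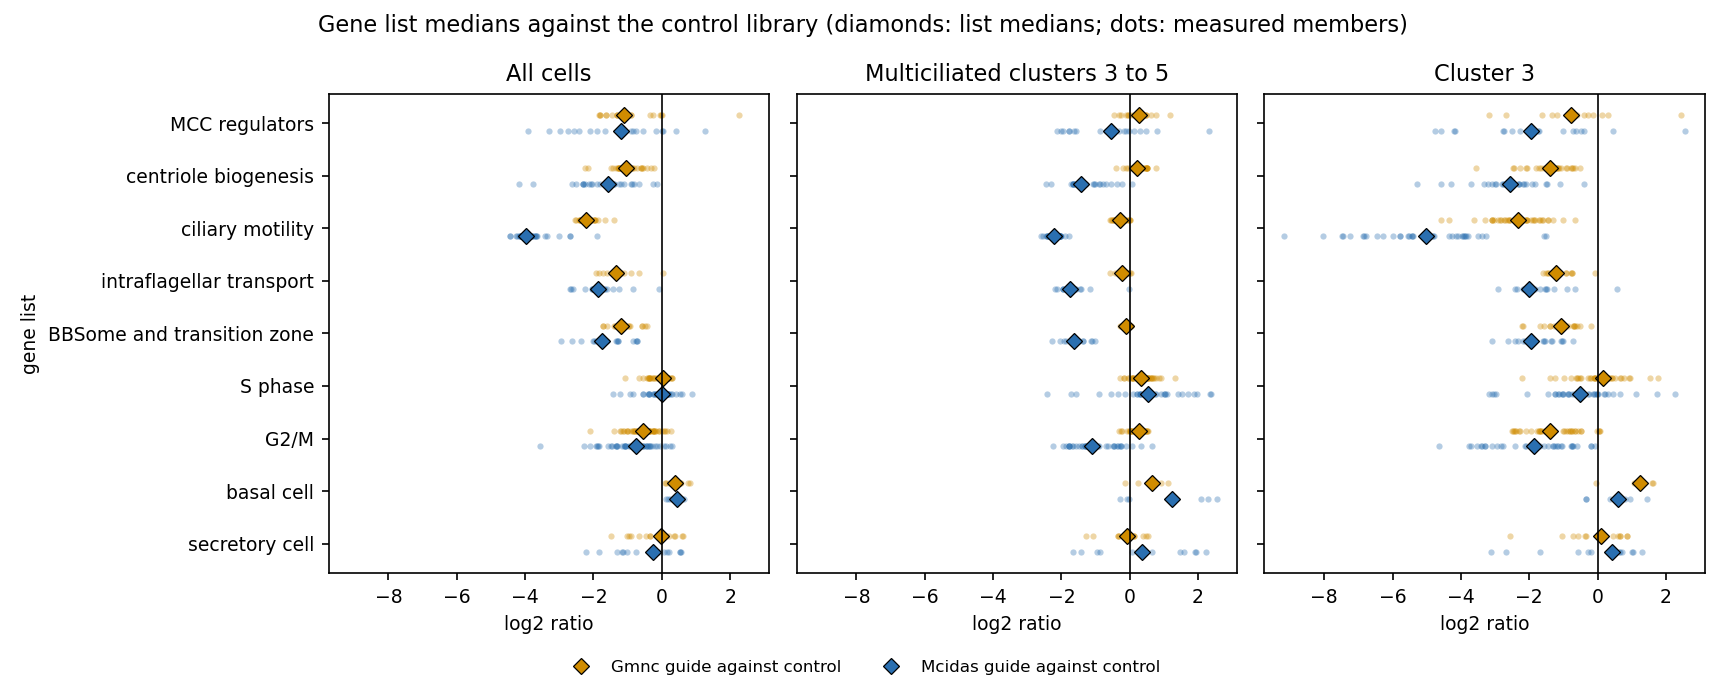
Each diamond is the median log2 ratio of a gene list and each dot a measured member, for the Gmnc guide (orange) and Mcidas guide (blue) libraries against the control, over all cells, clusters 3 to 5 and cluster 3. The ciliary motility medians are -2.21 and -3.97 over all cells, -0.29 and -2.22 in clusters 3 to 5, and -2.34 and -5.03 in cluster 3.

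The guide libraries were compared with each other to ask where Gmnc and Mcidas differ. Ciliary motility genes were lower in the Mcidas-labelled library, with 37 of 40 past 2-fold and a median of -1.73 over all cells. Mycl was the gene with the highest ratio, 5.39-fold higher at 93.9 against 17.4 CPM, and Ifit3 the gene with the lowest, 7.45-fold lower at 2.52 against 18.8 CPM. After Mycl came the DNA polymerase gene Pola1 (14.3 against 8.70 CPM), Dynap, Paqr4 (22.0 against 13.7 CPM), Cdkn1a (863 against 547 CPM), Ccl5, Krt16, Pnpla2 (107 against 74.4 CPM), Alkbh1 and Serpinb2. After Ifit3 came Dmkn, Ccdc153, Morn5, Lrrc23, Fam92b, Ccna1, the histidine decarboxylase gene Hdc, Tekt4 and Odf3b, with log2 ratios of -2.23 to -2.06. The predicted genes passed over numbered 2 with a higher and 1 with a lower ratio. Medians were -0.58 for centriole, -0.52 for intraflagellar transport, -0.49 for BBSome and transition zone and -0.20 for the regulators. Interferon response genes had a median of -0.63 (8 of 20 lower) and neuroendocrine markers one of -1.49 (3 of 4 lower). Foxj1 stood at 25.3 CPM in the Mcidas-labelled and 71.8 CPM in the Gmnc-labelled library.

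In clusters 3 to 5 the Mcidas-labelled cells were lower than the Gmnc-labelled cells in 40 of 40 ciliary motility genes (median -1.92) and 26 of 29 centriole genes (median -1.67). These values mix stages, since cluster 3 held 245 of the 342 Mcidas-labelled and 55 of the 312 Gmnc-labelled cells, and within cluster 3 the Mycl-led Leiden cluster held 243 and 36. In cluster 5 alone the ciliary median was -0.75 and the centriole median -0.75. There 16 of 64 Mcidas-labelled but 0 of 134 Gmnc-labelled cells fell in the Mycl-led Leiden cluster, so different cells are compared there too. Cyp2a5, Tnip3, Tceal9, Pigr, Mycl, Rad51b, Krt15 and the transferrin receptor gene Tfrc had the highest ratios, and Orm1, Dmkn, the mitotic kinase gene Melk, Cfap157, Rptoros, Paqr5, Dthd1 and Lrrc71 the lowest. In cluster 3 the ciliary median was -3.18 (30 of 32 lower), the centriole median -1.06 (15 of 26 lower) and the regulator median -1.18 (11 of 18 lower). There Foxj1 stood at 39.4 against 430 CPM, Plk4 at 8.56 against 94.5 CPM, Dynlrb2 at 0.920 against 134 CPM and Ccdc39, an axonemal ruler gene, at 4.05 against 52.7 CPM. Tppp3, Cfap45, Mns1 and Tuba1a were also among the lowest, and AU040972, Lpar1, Rad51b, Cyp2a5, Serpinb11, Pdzk1ip1, Gna14 and Ckmt1 the highest.

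Cell cycle genes, several of which serve centriole amplification in multiciliated cells, differed by stage. In cluster 3 the summed G2/M list stood at 5763 CPM in the control, 2916 CPM in the Gmnc-labelled library and 1983 CPM in the Mcidas-labelled library, and the S phase list at 1609, 1635 and 1015 CPM. In cluster 4 the G2/M sums were 11568, 11030 and 10091 CPM, the last from 33 cells. In cluster 5 they were 8830, 8836 and 5005 CPM. Tubb4b, which the ciliary list also holds, made up most of the G2/M sum over all control cells (4416 CPM). Its part was not separated within clusters, so these sums are not read as mitotic mRNA. In cluster 5, 16 of 64 Mcidas-labelled, 0 of 965 control and 0 of 134 Gmnc-labelled cells fell in the Mycl-led Leiden cluster. Over clusters 3 to 5 the G2/M sums were 9379, 8778 and 3557 CPM. Those cells were mostly cluster 3 in the Mcidas-labelled library and mostly cluster 5 in the control. Cdk1 was seen in 77.4%, 50.9% and 35.1% of thinned cluster 3 cells and Top2a in 33.6%, 12.7% and 4.49%. Ccnb1 was seen in 8.22% of control and 0.408% of Mcidas-labelled cluster 3 cells, and E2f7 in 40.4%, 47.3% and 19.2%. Mki67, the standard marker of proliferation, was seen in 0.685%, 1.82% and 0.816% of cluster 3 cells, against 64.8%, 61.7% and 56.7% of the cycling-like cluster 11, and Mcm5 in 2.06%, 3.64% and 3.27%. Ccna1, the meiotic A-type cyclin, was seen in 83.0%, 65.0% and 51.5% of cluster 4 cells, in 30.3%, 36.6% and 15.6% of cluster 5 cells, and in 10 of 146, 1 of 55 and 0 of 245 cluster 3 cells, the last allowing up to 1.22%. No cycling is read from these lists alone.

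Clusters 1, 6 and 9 were used as background for these differences. That they do not depend on the targeted genes was assumed and not tested. In the order control, Gmnc-labelled and Mcidas-labelled, Gmnc stood at 8.04, 22.45 and 10.9 CPM in cluster 1. It stood at 13.8, 48.8 and 23.2 CPM in cluster 6. How much of the ciliary mRNA in these clusters was free RNA was not tested. In the basal-like cluster 1 the ciliary motility medians were -1.65 for the Gmnc-labelled and -1.33 for the Mcidas-labelled library against the control, over 16 measured genes at low counts, and in cluster 9 they were -1.69 and -3.05. Interferon response genes had a median of 0.45 in cluster 1 of the Gmnc-labelled library, and secretory genes had medians of -0.19 and -0.32. Scgb3a2, a secretoglobin, stood at 500 CPM in the control, 166 CPM in the Gmnc-labelled library and 119 CPM in the Mcidas-labelled library in cluster 1, and Akr1c18 at 62.8, 99.4 and 86.8 CPM. In the secretory-like cluster 6 the ciliary medians were -1.56 and -1.92 and the secretory medians 0.00 and -0.35.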

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

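Among the tests of explanations in this part, those on the Mycl-led cells were chosen before the results they measure were seen, and those on cluster 3 and on Gmnc mRNA were chosen only after. None of the differences between libraries listed here was itself tested, since each group has 1 library.

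The share of cluster 3, the earliest multiciliated-like cluster, lay below the control in the Gmnc-labelled library and above it in the Mcidas-labelled library, at 1.11% and 5.20% against 2.77%. The barcodes that the authors left out were shallower in genes and richer in mitochondrial counts than kept cells, unequally between libraries, with medians of 2168 genes and 14.8% in the control, 2958 genes and 19.7% in the Gmnc-labelled and 2579 genes and 20.5% in the Mcidas-labelled library, and the accuracy of placing them in clusters was checked on kept cells only. Among them, those nearest to cluster 3 made up 0.733% and 2.15%, against 2.30% in the control. Myb, an early transcription factor of multiciliated cells, also went opposite ways in cluster 2, with a log2 ratio of 1.66 in the Mcidas-labelled library (24.0 against 7.29 CPM) and -1.61 in the Gmnc-labelled library (2.06 CPM). Mycl-led cells made up 30.4% of the Mcidas-labelled, 2.45% of the control and 0.644% of the Gmnc-labelled cluster 2 cells, and Myb stood at 56.8 CPM in those of the Mcidas-labelled library and 8.10 CPM in its other cluster 2 cells. Left-out barcodes nearest to cluster 1 made up 15.6% in the Gmnc-labelled and 13.5% in the Mcidas-labelled library, against 8.11% in the control. Left-out barcodes nearest to cluster 2 made up 75.3% and 79.3%, against 65.2% in the control. Those nearest to cluster 5 made up 1.74% in the Gmnc-labelled and 0.325% in the Mcidas-labelled library, against 16.3% in the control. That difference by itself raises the other shares. Left-out barcodes nearest to the interferon-rich cluster 7 made up 1.12% in the Gmnc-labelled library, with 92 barcodes, against 0.113% and 10 barcodes in the control.

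Cells led by Mycl, Pidd1, Paqr4 and Ccno made up 21.8% of the Mcidas-labelled library and 1.56% of the control, and held Mycl at 240 CPM, Ccno at 112 CPM and Myb at 80.9 CPM with little Foxj1 (15.0 CPM) or Plk4 (3.90 CPM). Doublets of an early multiciliated cell and a cluster 2 cell would need about 1.5 times the UMIs of other cluster 2 cells or more, and the ratio was 1.19. Dividing cells would need G2/M mRNA near that of cluster 11, and these cells held 14.6% of it. That list includes Tubb4b, and it summed to 1564 CPM here, 1295 CPM in the other cluster 2 cells and 10708 CPM in cluster 11. Mki67 stood at 0.650 CPM in these cells and 302.5 CPM in cluster 11, Top2a at 4.88 and 601 CPM, and E2f7 at 20.1 and 18.7 CPM. The S phase list of these cells summed to 732 CPM, against 4163 CPM in cluster 11 of the Mcidas-labelled library. Mycl-led cells of the control and Gmnc-labelled libraries held 1134 and 1152 CPM, with 35 of 82 and 36 of 53 from cluster 3. That cluster gave 243 of the 1026 Mcidas-labelled ones. Mcidas-labelled Mycl-led cells of cluster 2 summed to 637 CPM, although the other cluster 2 cells held 458 CPM. An offset of the whole library would raise their 10 leading genes elsewhere as in cluster 2 (median log2 ratio 1.26). The median over clusters 1, 6, 9, 10 and 11 was 0.26, from -0.197 in cluster 9 to 0.574 in cluster 6. Those genes were chosen as leading a cluster made mostly of Mcidas-labelled cells of cluster 2, so a higher ratio there was fixed in advance. No conclusion on an offset is drawn from this comparison. An effect of the Mcidas guide and a difference between cultures stay open and were not tested.

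Cluster 3 cells of the Mcidas-labelled library held less ciliary and centriole mRNA than those of the control, with medians of -5.03 and -2.55. Position on the authors' pseudotime alone would account for part of this at most, because at matched pseudotime the centriole median was still -2.0. Free RNA from the control's more numerous multiciliated cells would be lowered by the authors' correction, and the ciliary median with the corrected counts was -5.14. How well that correction removes free ciliary RNA was not checked, so no conclusion on free RNA is drawn. The class holds different cells in each library, since 243 of 245 Mcidas-labelled cells but 35 of 146 control cells fell in the Mycl-led Leiden cluster, and 2 and 110 in a Deup1-led one, so a difference in stage that pseudotime does not capture stays open. An effect of the Mcidas guide on these genes stays open and was not tested, and a difference between cultures stays open as well.

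Gmnc mRNA was higher, not lower, in the Gmnc-labelled library. A larger share of cluster 2 cells, in which Gmnc is a leading gene, would leave little difference within that cluster, and the log2 ratio there was 2.11. Free RNA would be lowered by the correction, and the ratio with the corrected counts was 2.33. How well the correction removes free Gmnc RNA was not checked, so no conclusion on free RNA is drawn. The Mcidas-labelled library, whose log2 ratio was 1.28, also held more Gmnc mRNA. An effect of the guide, a difference between cultures and a mix-up of libraries stay open and were not tested, since 3′ UMIs do not read the target site.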

How the results depend on the processing

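The alternatives that used corrected counts, the highest Scrublet scores, matched pseudotime, cluster 3 alone, Leiden clusters without regulators and the Mycl-led cluster were chosen after seeing the data, and the others were planned. No leave-one-out was possible, and no paired analysis was possible because each group has 1 library and the labels give replicate number 1 only. Scrublet at its default threshold removed 1 cell, so that alternative tests nothing, although the counts of inside and outside values below include it. A list median counted as moved when it left its 95% bootstrap interval, and a share or a level when it left its counting interval. The counting interval of a gene ratio was computed without the added CPM, but the ratios set against it include that addition. A gene ratio can lie outside for that reason alone, so the inside and outside counts of gene ratios do not measure dependence on processing.

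Direction held under every alternative run for the ciliary medians against the control over all cells, in clusters 3 to 5 and in cluster 3, and for the all-cell log2 ratios of Gmnc in the Gmnc-labelled and Mcidas in the Mcidas-labelled library, of which 6 values were inside their intervals and 4 outside. The share of cells with a Mcidas UMI did depend on depth, at 13.9% in the control and 14.1% in the Mcidas-labelled library without thinning and 5.36% and 2.95% at 5000 UMIs. Of the main list medians 121 were inside and 19 outside, and of the other list medians 1626 were inside, 105 outside and 2 reversed. Of the class shares 22 were inside and 17 outside, and of the Foxj1 shares 6 and 9. Of the named genes 493 were inside, 356 outside and 1 reversed. A change of sign counted as reversed only for main values of at least 0.5 log2 units. Of 161 list medians 88 were smaller than that, and 25 of them changed sign under at least 1 alternative, as did 2 of 5 such gene ratios, and the direction of those that did is not read. The tuft median of the Mcidas-labelled library (0.45) ran from -0.21 to 0.61. Its ionocyte median (-0.60) ran from -1.20 to -0.31 and its neuroendocrine median (-0.89) from -0.97 to -0.015. In the Gmnc-labelled library the ionocyte median (-0.57) ran from -0.80 to -0.25 and the neuroendocrine median (0.88) from 0.36 to 1.31. Except where stated, the cause was not tested.

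With all barcodes of at least 500 genes the multiciliated share was 24.2% in the control, 4.45% in the Gmnc-labelled and 4.02% in the Mcidas-labelled library, and the cluster 3 share of the last was 3.20%. With the stricter cell filter it was 32.0% in the control and 7.31% in the Gmnc-labelled library. The marker rule gave 54.5%, 24.4% and 22.9%, but 48.0%, 26.3% and 22.4% of cluster 1 cells and 20.0%, 4.98% and 2.56% of cluster 9 cells met it, so it does not measure the multiciliated share. Leiden clusters gave 5.60% in the Gmnc-labelled and 1.78% in the Mcidas-labelled library, and without regulators 5.48% and 1.74%. With the Mycl-led cluster counted, the control and Mcidas-labelled shares were 30.9% and 23.6%, and without regulators 30.7% and 22.0%, so the size of the Mcidas-labelled class rests on whether those cells are counted.

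Over all cells the ciliary median of the Gmnc-labelled library was -2.14 with size factors, -2.13 with TMM, -2.16 with a pseudocount of 2, -2.40 with per-cell means, -2.14 with stricter cells and -2.40 with thinned cells. That of the Mcidas-labelled library was -3.81 with TMM, -4.07 and -3.69 with pseudocounts of 0.1 and 2, -4.13 with per-cell means and -4.10 with thinned cells. In clusters 3 to 5 that of the Mcidas-labelled library was -1.98 with size factors, -1.99 with TMM, -2.31 with per-cell means and -2.32 with thinned cells, and in cluster 3 it was -5.68 with a pseudocount of 0.1, which weighs genes near 0 more. At matched pseudotime in cluster 3 the Gmnc-labelled centriole and ciliary medians were -0.81 and -1.93, and the Mcidas-labelled centriole median was -2.0.

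The log2 ratio of Gmnc in the Gmnc-labelled library was 2.24 with all barcodes. That of Mcidas in the Mcidas-labelled library was -1.11 with size factors, -1.09 with TMM and -1.17 with all barcodes. The share of cells with a Foxj1 UMI was 59.1%, 25.6% and 19.1% without thinning, 23.2%, 5.84% and 3.14% at 2000 UMIs and 39.5%, 13.5% and 9.05% at 10000 UMIs, in the order control, Gmnc-labelled and Mcidas-labelled, as depth sets the chance of seeing a UMI.

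Reversed values of at least that size were the cluster 3 medians of the Mcidas-labelled library for p53 response (-0.030) and interferon response (-0.17) with thinned cells, and Scgb3a1 in clusters 3 to 5 of the Gmnc-labelled library (0.39) with all barcodes, and the cause was not tested.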

Other observations

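The values in this part were chosen after they were seen, and no explanation was tested for them. A few secretory genes, picked after being seen, were lower in both guide libraries, although the fixed secretory list had medians of 0.00 and -0.35 in cluster 6 and Cyp2f2 and Cbr2 were higher over all cells. In cluster 2 the secretoglobin gene Scgb3a2 stood at 3715 CPM in the control, 685 CPM in the Gmnc-labelled library and 321 CPM in the Mcidas-labelled library, Scgb1a1, the classic club cell marker, at 146, 40.3 and 28.9 CPM, and the paraoxonase gene Pon1 at 208, 52.6 and 28.3 CPM. In the secretory-like cluster 6, Scgb3a2 stood at 6347, 1563 and 1678 CPM and Scgb1a1 at 301, 122 and 91.9 CPM. The secreted-protein gene Bpifb1 differed there between the guide libraries, at 54.6 CPM in the control, 72.1 CPM in the Gmnc-labelled and 17.7 CPM in the Mcidas-labelled library. A Leiden cluster led by Scgb3a2, Pon1 and Upk3a held 15.4% of control cells, 6.69% of Gmnc-labelled cells and 2.31% of Mcidas-labelled cells, whereas one led by A2ml1, Tmprss11a and Gmnc held 2.83%, 17.6% and 9.32%.

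Interferon-induced genes were higher in the Gmnc-labelled library in more than cluster 7. In cluster 9, 14 of 18 measured members were at least 2-fold higher than in the control (median 1.90), with Ifit3 at 60.2 against 10.3 CPM, Isg15 at 123 against 26.0 CPM and Bst2 at 181 against 61.1 CPM, while the Mcidas-labelled library had a median of 0.28. Cluster 10, which shares basal and squamous keratins, held more ciliary mRNA in the control, with ciliary motility medians of -3.37 and -3.48 in the Gmnc-labelled and Mcidas-labelled libraries. Tppp3 stood at 239, 7.32 and 13.5 CPM, and Dynlrb2 at 91.3, 5.91 and 4.73 CPM. In cluster 11 Scgb3a1 stood at 3666, 238 and 1595 CPM. In the late multiciliated-like cluster 5, Krt15 stood at 1860 CPM in the Mcidas-labelled library against 375 CPM in the control, and Reg3g at 8918 against 2836 CPM. There 16 of 64 Mcidas-labelled but 0 of 965 control cells fell in the Mycl-led Leiden cluster, so different cells are compared.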
